A study of Mus musculus with 10 samples.

How the data were processed

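Regulatory T cells (Treg) carrying the YFP-Cre reporter driven by Foxp3 were sorted as YFP-positive cells from spleen and lymph nodes of female C57BL/6 littermates, per the labels' protocols. All mice were heterozygous for the Foxp3 YFP-Cre allele. Control mice carried 1 floxed Tfam allele, so the control cells also lose 1 copy where Cre acts, and the knockout (KO) mice carried the floxed allele on both chromosomes. Each RNA library was made from cells pooled from 2 to 3 mice, with DNase treatment, poly(A) selection and an NEBNext Ultra II RNA kit. There were 3 control and 3 KO libraries. The labels do not say whether pools of different numbers came from different litters or days, so the p-values measure the spread between these pools, which may be partly technical. ATAC-seq libraries, 2 per genotype, were not analysed here.

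The values used were read counts per gene, which the authors deposited as 1 table with 1 column per RNA library. The labels describe it as HTSeq counts. The submitters' processing notes also name HISAT2, Cufflinks, DESeq2, Bowtie2, SAMtools and bedtools and the builds mm10 and mm9, with no role for either build; versions, the annotation and the strand setting of the counting are not given in the sources used here. No coordinates are therefore printed. Genes that overlap on opposite strands cannot be told apart if the counting ignored strand, and genes with near-identical copies, such as classical and non-classical class I MHC genes, share reads. The counts were whole numbers that summed to 26300449, 21419772 and 27490253 in control replicates 1 to 3 and to 23794028, 20707030 and 19087757 in KO replicates 1 to 3. In the shallowest library a count of 3 equals 0.157 CPM (counts scaled to the library total), and in the deepest 0.109 CPM. Intervals and floors cover counting error only. Every line of the table named an Ensembl gene. Of 22553 Ensembl gene IDs, 22522 matched a symbol in the gene name table; the remaining 31 held 0.00269% of the counts.

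Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 2 groups (minimum count 10, minimum total 15), which left 11990 genes. Libraries were scaled with TMM factors, which lay between 0.9899 and 1.0274, and KO was compared with control by the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over libraries. For 3 genes with few counts in KO, the ratio of summed counts, each divided by the summed TMM-scaled library sizes of its group, was given with an exact binomial 95% interval, which covers counting noise only.

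A total of 38 gene lists were fixed before the data were examined, as were the test, the rule for named genes and the alternatives other than those marked below. Lists with at least 3 tested members (36 of 38) were tested with camera in limma 3.58.1 on the same fit, with a preset correlation of 0.01 between genes and adjustment over the 36 lists. Camera compares a list with all other genes. It was rerun with the correlation estimated from the data, and fry was run as a test of whether the genes of a list move one way on balance. Calls within a list were also counted with p-values adjusted over the list alone. The named genes were Tfam, Foxp3, Il2ra and Ctla4; the mtDNA-encoded protein genes as a group; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out unnamed models, pseudogenes and antigen receptor segments; and, for each list, up to 4 called members with the smallest adjusted p, or the 2 most abundant tested members where none was called. Genes named outside this rule, among them Klrg1, Il10 and those named for a call with the replicate block, were chosen after their values were seen. The values of a few genes that this rule names are not reported here.

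The test was checked on simulated counts drawn from the real means, library sizes and dispersions of the 11990 genes, with 200 genes changed in each of 5 runs. At 4-fold, 96.7% of changed genes were called in the right direction, at 2-fold 79.4% and at 1.5-fold 56.1%. Unchanged genes made up 7.37% of the calls, counting only them and the rightly directed calls on the 200 genes. Calls on 30 further genes, shifted as a list in the same runs, were left out of that share. This simulated list of 30 genes, shifted by 0.3 on the log2 scale, was called in 5 of 5 runs, and 0 of 150 unchanged lists were called. The simulated genes were independent of each other, so this does not cover correlated lists.

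Libraries of 1 group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 8.79 to 27.8 over the genes with at least 20 counts. None therefore repeats another, and each library was counted once. This cannot tell separate pools from separate preparations of 1 pool, which could also differ by more than that noise. Both groups have replicates numbered 1 to 3 in the labels, with no stated meaning of the number. Deviations of log2 CPM from the group means correlated across genes at 0.30, 0.58 and 0.54 between same-numbered libraries and at -0.55 to 0.02 between the others. A gene's 3 deviations sum to 0 within each group, so positive same-number values push the others below 0. The others are therefore no separate evidence of pairing. Because each of the 3 same-numbered correlations was over 0.1, the numbers were taken to pair the libraries, and fits with the replicate number as a block are given where they change a call or a count by over 1.5 times.

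The alternatives tried were size factors of DESeq2, upper quartile factors, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, a minimum of 2-fold, an adjusted p under 0.01, and leaving out each library in turn. The fits with 1 library left out did not include the block, so calls lost in them do not take the pairing into account. Chosen after seeing the data were leaving out both libraries numbered 2, DESeq2 with the block, thinning to the smallest library, the block with a minimum of 2-fold, and camera with an estimated correlation, or fry, with the block. All 13 mtDNA-encoded protein genes were listed at 0 in all 6 libraries, and the 2 mtDNA-encoded rRNA genes were not used here. The test of the share of counts from mtDNA and the alternatives tied to it were not run, since mitochondrial transcripts are not measured by this table. Figures were drawn with matplotlib 3.10.9.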

Results

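The series asks how regulatory T cells depend on TFAM, the protein that packages mitochondrial DNA (mtDNA) and is needed for its transcription. Treg are the Foxp3-expressing CD4 T cells that restrain immune responses. Poly(A) RNA was sequenced from YFP-positive Treg of spleen and lymph nodes, in 3 control libraries with 1 floxed Tfam allele and 3 KO libraries with both alleles floxed. Each library pooled cells of 2 to 3 mice. The control libraries held between 21419772 and 27490253 gene counts and the KO libraries between 19087757 and 23794028 (n = 3 each).

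Tfam (ENSMUSG00000003923) fell 2.13-fold in KO, a log2 fold change of -1.09 ± 0.17 (SE, adjusted p = 0.020). Its level was 25.9, 30.6 and 42.4 CPM in control replicates 1 to 3 and 15.6, 14.4 and 16.5 CPM in KO replicates 1 to 3, so the 2 groups did not overlap and no library contradicted its label. Counts were summed over the whole gene, so reads from exons outside the deleted part remain in them and the residual KO level does not measure intact mRNA. The direction held with every library left out, at log2 fold changes between -1.22 and -0.87. The call was lost without control replicate 2 (adjusted p = 0.0551), KO replicate 1 (0.109), KO replicate 2 (0.0866) or KO replicate 3 (0.0844). These fits did not include the replicate block. With the block and all libraries, edgeR called Tfam lower at an adjusted p of 0.000125. Foxp3 (ENSMUSG00000039521), the transcription factor that defines the lineage, stood at 744 ± 95.3 CPM in control and 818 ± 47.97 CPM in KO (log2 fold change 0.14 ± 0.10, adjusted p = 0.613). Il2ra (ENSMUSG00000026770), the high-affinity IL-2 receptor chain, stood at 313 ± 3.45 and 323 ± 4.62 CPM (0.05 ± 0.06, adjusted p = 0.792). Ctla4 (ENSMUSG00000026011), an inhibitory receptor, stood at 223 ± 31.99 and 192 ± 29.08 CPM (-0.22 ± 0.13, adjusted p = 0.535), and was called lower with the replicate block in edgeR (adjusted p = 0.0432) but not in DESeq2 (adjusted p = 0.0901).

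**Figure D1:**
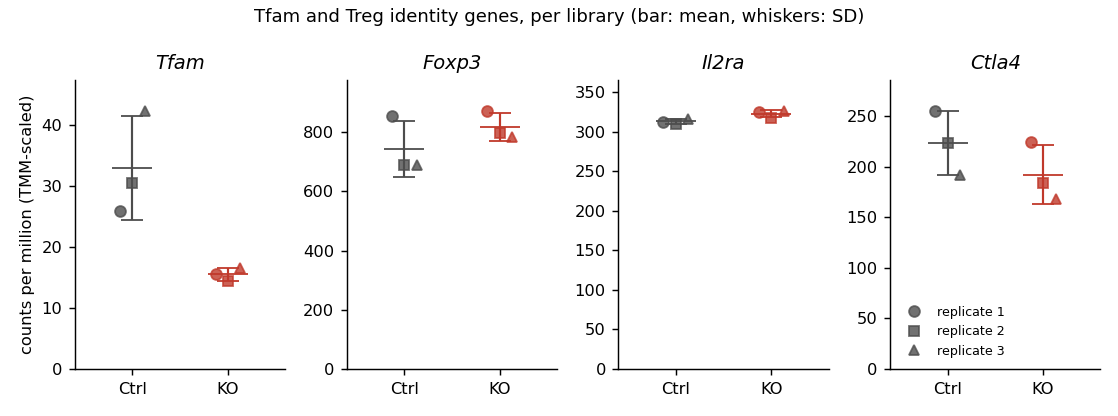
TMM-scaled CPM of Tfam, Foxp3, Il2ra and Ctla4 in each of the 3 control (Ctrl) and 3 KO libraries, with the mean as a bar and the SD as whiskers. Tfam lies between 25.9 and 42.4 CPM in control and between 14.4 and 16.5 CPM in KO, while the ranges of Ctla4 overlap.

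Among called genes with a mean of at least 5 CPM, 10 named genes had the largest falls. The chemokine receptors Cxcr3 and Ccr2, which guide T cells into inflamed tissue, fell 6.53-fold (log2 fold change -2.71 ± 0.15, adjusted p = 0.000434) and 7.59-fold (-2.92 ± 0.22, adjusted p = 0.00141). Tigit, a co-inhibitory receptor, fell 7.66-fold, from 30.57 ± 5.46 to 3.96 ± 0.72 CPM (SD, n = 3 each; adjusted p = 0.000434). Fgl2, a secreted suppressive protein, fell 4.53-fold, and Il9r, the IL-9 receptor chain, 5.66-fold. The calcium-binding proteins S100a4 and S100a6 fell 6.32-fold and 5.39-fold, the transcription factor Tox2 6.77-fold and Ttc39c 7.76-fold. H2-Bl, a class I MHC gene, had a fitted fall of 8.66-fold, which is uncertain because its reads can be shared with near-identical MHC genes. These 10 genes had adjusted p-values between 0.000434 and 0.00798. Of the 10, 7 were called whichever library was left out, while H2-Bl (adjusted p = 0.0621), S100a4 (0.066) and S100a6 (0.066) were not called without KO replicate 1.

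**Figure D2:**
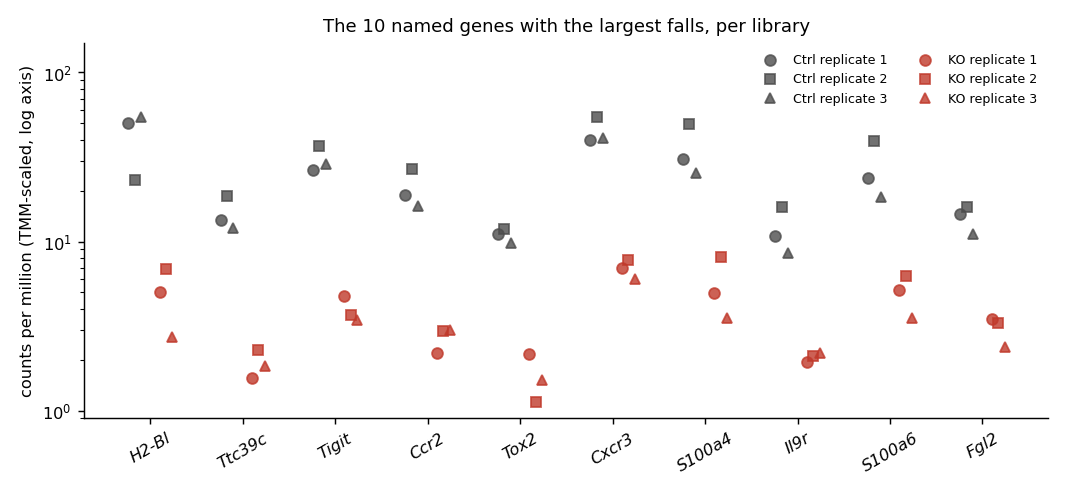
TMM-scaled CPM, on a log axis, of the 10 named genes with the largest falls in the 3 control (Ctrl, grey) and 3 KO (red) libraries; the marker shape gives the replicate number. For each gene the 3 KO libraries lie below the 3 control libraries.

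The rises were small. Als2cl rose 1.62-fold, from 203 ± 28.49 to 329 ± 33.41 CPM (log2 fold change 0.70 ± 0.11, adjusted p = 0.0226), and Palm3 1.62-fold. Clcf1, a cytokine of the IL-6 family, rose 1.41-fold (adjusted p = 0.020), and Rasgrp2, an activator of the small GTPase Rap1, 1.27-fold, from 394 ± 18.89 to 501 ± 15.58 CPM (adjusted p = 0.0451). Zfp950, Hid1, Col11a2, Lgals4, Rhbdl1 and Fam189b had log2 fold changes between 0.34 (Fam189b) and 0.59 (Zfp950). Palm3, Zfp950, Col11a2, Lgals4, Rhbdl1, Rasgrp2 and Fam189b were not called by limma-voom. Of these 10 rises, 0 were called in every fit with 1 library left out and 6 (Palm3, Zfp950, Hid1, Lgals4, Rhbdl1 and Rasgrp2) were called in none. Als2cl, Col11a2 and Fam189b were called only without control replicate 1, and Clcf1 only without control replicate 1 or 3. Where a call was lost, the adjusted p lay between 0.0539 (Als2cl without KO replicate 2) and 0.254 (Zfp950 without KO replicate 1). The one gene called higher by at least 2-fold, the unnamed model 1700029J07Rik, averaged 0.898 CPM.

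Over all 11990 tested genes, 167 were called lower and 12 higher in KO by edgeR. Of the lower genes, 104 fell by at least 2-fold, and the median log2 fold change was -1.27, against 0.46 for the higher ones. All 179 called genes had non-overlapping groups. Chance alone gives this for 10% of unchanged genes, but the call itself selects for such genes, so it adds no support. With the replicate block 526 genes were called lower and 236 higher, among them all 179, each in the same direction. DESeq2 called 261 lower and 72 higher, and limma-voom 136 lower and 3 higher. The number of lower genes was 84 without control replicate 1, 82 without control replicate 2, 26 without KO replicate 1, 61 without KO replicate 2 and 63 without KO replicate 3. The number of higher genes was 0 without control replicate 2 or any of the KO replicates and 1 without control replicate 3. Without both libraries numbered 2, left out after seeing the data because they held the most myeloid RNA, 54 genes were called lower and 0 higher.

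Effector and tissue Treg genes, a list of 47 receptors, transcription factors and effector molecules known from activated and tissue-resident Treg, formed the group with the lowest median. Of the 47 genes, 25 fell, 0 rose and 22 did not pass, and 33 were lower when adjusted over the list alone. The median log2 fold change was -0.91, and it was -0.92, -1.04 and -0.82 within same-numbered pairs 1 to 3. Besides Cxcr3 and Ccr2, Gzmb, a cytotoxic granule protease, fell 6.59-fold (-2.72 ± 0.22, adjusted p = 0.00141) and Il1rl1, the IL-33 receptor, 3.46-fold (-1.79 ± 0.15, adjusted p = 0.00171). Among members named after their values were seen, the skin and lung homing receptor Ccr4 fell 3.32-fold, Ccr6 1.99-fold and Ccr8 1.79-fold. The transcription factors Maf, Prdm1 and Batf fell 2.28-fold, 1.90-fold and 1.53-fold. Klrg1, a marker of terminally differentiated Treg, had 418 counts over the 3 control libraries and 3 over the KO libraries, all 3 in KO replicate 1, a depth-scaled ratio of 117 (95% interval 39.7 to 569). Il10, a suppressive cytokine, had 231 against 16 counts, 11 of the 16 in KO replicate 1, a depth-scaled ratio of 12.1 (7.3 to 21.6). Without KO replicate 1 the log2 fold change moved from -6.75 to -10.02 for Klrg1 and from -3.61 to -4.56 for Il10. Klrg1 then had 0 counts in KO, so its value of -10.02 is not a measured size. By camera the list was lower than other genes (adjusted p = 3.5e-82, or adjusted p = 0.117 with an estimated correlation). It was also called by fry (adjusted p = 0.048), but not by fry with the replicate block (adjusted p = 0.0521). The list's camera call held with each library left out, but its number of lower genes was 8 without KO replicate 1, 13 without KO replicate 3, 15 without KO replicate 2 and 17 without control replicate 1 or 2. Of the genes named here, Cxcr3, Ccr2, Gzmb, Il1rl1, Klrg1 and Maf were called whichever library was left out. Without KO replicate 1 the adjusted p was 0.0543 for Ccr4, 0.0602 for Ccr6, 0.066 for Ccr8, 0.166 for Prdm1, 0.115 for Batf and 0.0538 for Il10. Ccr4 and Batf were also not called without KO replicate 2 (0.0539 for both) or KO replicate 3 (0.0514 and 0.0697), and Batf without control replicate 2 (0.0566). Ccr8, Prdm1 and Il10 were called only with all libraries or without control replicate 3, with adjusted p-values of 0.0869, 0.0877 and 0.0732 without control replicate 1, 0.0905, 0.078 and 0.0627 without control replicate 2, 0.102, 0.0859 and 0.0586 without KO replicate 2 and 0.0898, 0.12 and 0.0968 without KO replicate 3.

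The Treg core signature, 33 genes that distinguish Treg from conventional T cells, leaned lower, with 26 of the 33 fitted below 0. Of the 33 genes, 9 fell, 0 rose and 24 did not pass, with 19 lower when adjusted over the list alone and 18 lower and 1 higher (Gpr83) with the replicate block. The 9 were Tigit, Penk, Gzmb, Fgl2, Il10, Itgae, Icos, Nrp1 and Cst7, and Il10, Gzmb and Itgae are also in the effector list. Penk, which encodes an opioid peptide precursor, fell 2.74-fold (-1.45 ± 0.10, adjusted p = 0.00114). Itgae, the CD103 integrin chain that binds E-cadherin, fell by 1.30 on the log2 scale, from 121 ± 32.21 to 49.16 ± 9.41 CPM, the costimulator Icos 1.96-fold and the co-receptor Nrp1 1.51-fold. By contrast Ikzf2, the transcription factor Helios, had a log2 fold change of -0.14 ± 0.16 (adjusted p = 0.758) and Lrrc32, the docking receptor for latent TGF-beta, of -0.001 ± 0.12 (adjusted p = 0.998). Itgae, Icos, Nrp1, Ikzf2, Lrrc32 and Gpr83 were named after their values were seen. The median of the list was -0.32, and camera called it lower (adjusted p = 8.93e-28, or adjusted p = 0.0907 with an estimated correlation). It was also called by fry (adjusted p = 0.0403; 0.0521 with the block). The number of lower genes was 4 without KO replicate 1 or 3 and 5 without KO replicate 2. Itgae was not called without KO replicate 1 (adjusted p = 0.112) or 3 (0.0887), Nrp1 without KO replicate 1 (0.121), 2 (0.0874) or 3 (0.0968), and Icos without KO replicate 1 (0.116), 2 (0.0874), 3 (0.0933) or control replicate 1 (0.0557).

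Helper T cell cytokines and regulators had 5 of 18 tested genes lower, 0 higher and 13 not passed, and 7 lower when adjusted over the list alone. The 5 were the IL-18 receptor chains Il18rap (5.18-fold, adjusted p = 0.00798) and Il18r1 (log2 fold change -0.84 ± 0.11, adjusted p = 0.0105), the ligand Tnfsf11 (1.47-fold, adjusted p = 0.0263), the cytokine Ifng (3.23-fold, from 3.54 ± 1.23 to 1.08 ± 0.12 CPM, adjusted p = 0.0377) and the decoy receptor Il1r2 (adjusted p = 0.0392), the last named after its values were seen. The list median was -0.14 and camera called it lower (adjusted p = 2.96e-06, or adjusted p = 0.187 with an estimated correlation), as did fry (0.048; 0.23 with the block). The number of lower genes was 0 without KO replicate 1, 2 without KO replicate 2, KO replicate 3 or control replicate 2, and 3 without control replicate 1. Ifng and Il1r2 were not called by limma-voom. Without both libraries numbered 2, Il18r1, Tnfsf11, Ifng and Il1r2 lost their calls. Il18rap lost its call without KO replicate 1 (adjusted p = 0.066) and Il18r1 without KO replicate 1 (0.077) or 2 (0.0578). Tnfsf11 and Ifng lost theirs without control replicate 1 (0.0869 and 0.103), control replicate 2 (0.116 and 0.115), KO replicate 1 (0.166 and 0.181) or KO replicate 3 (0.108 and 0.154), and Ifng also without KO replicate 2 (0.125). Il1r2 kept its call only without control replicate 1; its adjusted p was 0.113 and 0.0932 without control replicates 2 and 3 and 0.179, 0.0927 and 0.142 without KO replicates 1 to 3.

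Central Treg and quiescence genes, which mark recirculating lymphoid Treg, were the 1 list called higher by camera (adjusted p = 0.0275, or adjusted p = 0.796 with an estimated correlation). Its 27 genes had a median of 0.07, and 0 passed over all genes; adjusted over the list alone, the survival gene Bcl2 (0.31 ± 0.07) was higher and the follicular homing receptor Cxcr5 (-0.68 ± 0.14) lower, both named after their values were seen. With the block, Bach2, Bcl2 and Satb1 were called higher and Cxcr5 lower. Without the block, DESeq2 called Bcl2 and Cxcr5, and edgeR with no filter on low counts called Cxcr5. Its most abundant members, Ets1 and Klf2, had log2 fold changes of 0.04 ± 0.08 and -0.03 ± 0.26. The call was lost without control replicate 2 (adjusted p = 0.28), KO replicate 1 (adjusted p = 0.072) or both libraries numbered 2 (adjusted p = 0.247).

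Genes of mitochondrial function encoded in the nucleus moved little. The 13 mtDNA-encoded protein genes were listed at 0 in all 6 libraries, so the transcripts that TFAM acts on are not measured here. Of the 27 tested genes for mtDNA maintenance and transcription, a list without Tfam itself, 0 passed; Polg, the mtDNA polymerase, had a log2 fold change of 0.11 ± 0.08 and the coactivator Pprc1 of 0.23 ± 0.07, called with the replicate block in edgeR (adjusted p = 0.0302) but not in DESeq2 (0.0519). The list had a median of 0.07 and was not called by camera (adjusted p = 0.0716), but was called higher without control replicate 3 (0.0334) or KO replicate 1 (0.0459) and with no filter on low counts (0.0218). The nuclear-encoded subunits of complex I had a median log2 fold change of -0.11 over 37 genes, 0 of them called. Of the 37, 35 had a fitted value below 0, and Ndufv1 had the highest, at 0.02 ± 0.07. The 17 genes of ATP synthase had a median of -0.12 and all 17 had a fitted value below 0, with Atp5b at -0.08 ± 0.09 and Atp5a1 at -0.11 ± 0.07. Camera called complex I (adjusted p = 0.00959) and ATP synthase (adjusted p = 0.0107) lower; both had adjusted p = 0.796 with an estimated correlation. Both calls were lost without control replicate 2 (adjusted p = 0.0641 for complex I and 0.0613 for ATP synthase), control replicate 3 (0.0896 and 0.14) or KO replicate 3 (0.18 and 0.0886). With the block, Ndufa4 and Ndufb9 of complex I and Atpif1 of the ATP synthase list were called lower in edgeR (adjusted p = 0.0295, 0.0398 and 0.0363) but not in DESeq2 (0.162, 0.244 and 0.211). Complexes II, III and IV had medians of -0.11, -0.13 and -0.14 and were not called (adjusted p = 0.269, 0.193 and 0.0632), although complex IV was called without control replicate 1 (adjusted p = 0.0446), KO replicate 2 (0.00442) or both libraries numbered 2 (0.0103) and with no filter on low counts (0.0255). Their most abundant genes, Sdha, Sdhb, Uqcrc1, Uqcrc2, Cox4i1 and Cox6a1, had log2 fold changes between -0.14 and -0.04. Mitochondrial ribosomal proteins (median -0.07 over 78 genes; Mrpl24 -0.01, Mrpl9 -0.07), mitochondrial chaperones and proteases (0.01 over 19; Hspa9 0.04, Yme1l1 0.01) and genes of mitochondrial dynamics and mitophagy (-0.03 over 21; Sqstm1 -0.10, Tax1bp1 -0.01) had 0 called members each and adjusted p-values of 0.109, 0.76 and 0.419 by camera. The ribosomal protein list was called lower without control replicate 1 (adjusted p = 0.0172) or KO replicate 2 (0.0197), and with the block Ubl5 and Pink1 were called lower in the other two lists, though not in DESeq2 with the block (0.195 and 0.0558).

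Metabolic and stress programmes likewise had 0 called members each. Glycolysis had a median of -0.07 over 23 genes, with Gpi1 at -0.07 ± 0.07 and Pkm at -0.15 ± 0.09. The TCA cycle (median -0.04; Mdh2 -0.06, Ogdh -0.03), fatty acid oxidation (-0.08; Hadha -0.13, Acsl5 -0.16), fatty acid synthesis (0.01; Acly -0.06, Fasn 0.00) and cholesterol synthesis (-0.07; Srebf2 0.01) stayed within 0.1 of 0 in their medians. The ATF4 and amino acid response, the integrated stress programme known to follow mitochondrial translation defects, had a median of -0.001 over 39 genes, with Ppp1r15a at 0.01 ± 0.31 and Slc1a5 at 0.11 ± 0.08. Antioxidant genes (-0.09; Ucp2 -0.09, Tkt -0.13), endoplasmic reticulum stress genes (-0.09; Hspa5 -0.16, Pdia3 -0.14), lysosomal genes (-0.04; Psap 0.08, Ctss -0.08), MYC targets and ribosome biogenesis (0.01; Ncl -0.11, Npm1 -0.03), cytoplasmic ribosomal proteins (-0.02; Rpl4 -0.01, Rps3 -0.03) and the DNA methylation list (0.06; Dnmt1 0.07, Mbd2 -0.09) were not called by camera, with adjusted p-values from 0.0632 to 0.76. The antioxidant list was called lower without control replicate 1 (adjusted p = 0.0238), KO replicate 1 (0.0459), KO replicate 2 (0.00575) or both libraries numbered 2 (0.0256) and with no filter on low counts (0.00754). Cytoplasmic ribosomal proteins were called lower without KO replicate 2 (0.0112) or both libraries numbered 2 (0.0354). Median and mean differed in sign for fatty acid synthesis, MYC targets, mitochondrial chaperones, hypoxia (each with a positive median and a test upwards) and cytoplasmic ribosomal proteins (negative median, test downwards), and for the ATF4 list both were below 0 while the test pointed up; each of these had an adjusted p of 0.76 or 0.80. In the hypoxia list Hif1a, the oxygen-regulated transcription factor, had a log2 fold change of -0.34 ± 0.08 and was lower when adjusted over the list alone and with the replicate block (adjusted p = 0.00728), and Kdm3a stood at 0.09 ± 0.07. With the block, Idh3a, Hif1a, Wars, Ebp, Txn1, Atf6 and Odc1 were called lower in their lists, and Mcoln1 and Tet3 were called higher and Glb1, Gadd45b and Uhrf1 lower. Of these, DESeq2 with the block called only Hif1a, Odc1, Tet3, Glb1 and Gadd45b. Without the block, DESeq2 called Hif1a, Odc1 and Glb1, and edgeR called Odc1 when control replicate 3 was left out.

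Cell cycle genes had a median of -0.41 over 40 genes, 0 of them called and 37 with a fitted value below 0. Ccnd2 and Ccnd3, the most abundant, stood at 0.04 ± 0.11 and 0.10 ± 0.07. Camera called the list lower (adjusted p = 1.51e-05, or adjusted p = 0.796 with an estimated correlation), and 14 genes were called lower with the replicate block. Among these were the proliferation markers Mki67 (adjusted p = 0.000919) and Top2a (0.000467), named after their values were seen. Without the block their log2 fold changes were -0.96 ± 0.47 and -0.72 ± 0.35. The differences within pairs 1 to 3 were -0.16, -0.59 and -0.31, and the camera call was lost without control replicate 2 (adjusted p = 0.122) or KO replicate 3 (0.0516). Interferon-stimulated genes had 1 of 46 members lower, the chemokine Cxcl10 (4.34-fold, from 3.38 ± 1.26 to 0.77 ± 0.28 CPM, adjusted p = 0.0356), and 2 (Cxcl10 and Gbp3) when adjusted over the list alone. With the block 6 were called lower, Gbp3 among them, or 4 in DESeq2; Mx1, named after its values were seen, had a log2 fold change of -0.88 ± 0.26 (adjusted p = 0.204) and was called only with the block (adjusted p = 0.00446) and by DESeq2. Cxcl10 lost its call without any library but control replicate 3, at adjusted p-values of 0.0766 to 0.195, and was not called by limma-voom. DESeq2 without the block also called Gbp3. Camera called the list lower (median -0.23, adjusted p = 2.86e-06, or adjusted p = 0.796 with an estimated correlation). This rested on control replicate 1, without which the adjusted p was 0.278, and the within-pair medians were -0.63, 0.01 and -0.05. The p53 and apoptosis list had a median of -0.09 over 31 genes with 0 called (Mcl1 -0.03, Casp8 0.09); Bcl2 was higher and 2 genes, among them Bcl2l1, lower when adjusted over the list alone, and with the block 2 were higher and 5 lower, Bcl2l1 among the latter, or 1 and 2 in DESeq2, where Bcl2l1 was not called (adjusted p = 0.0816). Immediate early and heat shock genes had a median of -0.12 over 32 genes with 0 called (Junb -0.15 ± 0.26, Hspa8 -0.06 ± 0.10). The medians within pairs 1 to 3 went both ways, at -0.21, 0.17 and -0.27. With the block Nr4a2 was called lower in edgeR but not in DESeq2 (adjusted p = 0.139). Camera called this list lower without control replicate 3 (adjusted p = 0.0334), KO replicate 2 (0.0172) or both libraries numbered 2 (0.0175), against 0.387 with all libraries.

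**Figure D3:**
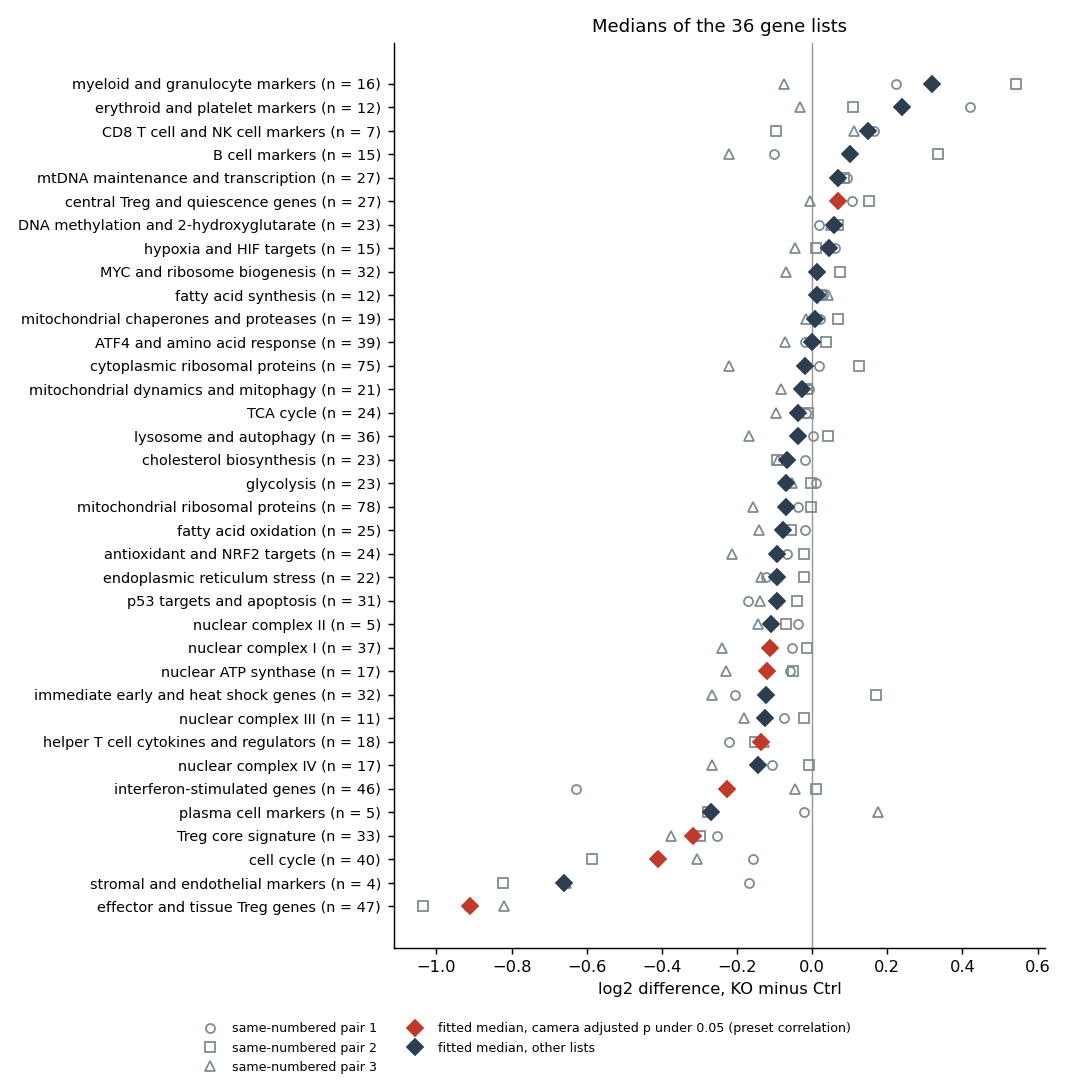
Median log2 difference between KO and control over the tested genes (n) of each of the 36 lists, fitted (filled diamonds) and within each same-numbered pair (open markers). The effector and tissue Treg list has the lowest median, -0.91; the red diamonds mark the 8 lists called by camera with a preset correlation, 0 of which were called with an estimated correlation.

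Markers of other cell types that a sort could hold were tested as lists. Of 15 tested B cell markers 1 fell, Ighm, the mu heavy chain constant region, by 1.38-fold, from 547 ± 15.99 to 395 ± 20.87 CPM (-0.47 ± 0.07, adjusted p = 0.0134). In the same libraries Cd79a, a B cell receptor chain, averaged 2.51 ± 0.43 CPM in control and 2.77 ± 0.81 CPM in KO. Cd22 was also lower when adjusted over the list alone, and Cd22 and Ighd with the block in edgeR (adjusted p = 0.0274 and 0.0344) but not in DESeq2 (0.171 and 0.107). Ighm lost its call without control replicate 2 (adjusted p = 0.059), KO replicate 1 (0.116) or KO replicate 2 (0.0774). Ighj1, a heavy chain joining segment outside the list and named after its values were seen, fell from 157 to 19 summed counts, a depth-scaled ratio of 6.94 (exact 95% interval 4.3 to 11.8; log2 fold change -2.77 ± 0.29, adjusted p = 0.00466), and was called with each library left out. The median of the 15 was 0.10, the mean -0.10 and the direction of the camera test down (adjusted p = 0.197, or 0.0289 without KO replicate 1). Within pairs 1 to 3 the medians were -0.10, 0.34 and -0.22. Of 7 tested CD8 T cell and NK cell markers the chemokine Ccl5 fell 3.28-fold (adjusted p = 0.00798) and Nkg7 1.69-fold (adjusted p = 0.0451); Nkg7 lost its call with any 1 library left out, at adjusted p-values of 0.0566 to 0.175. The median of the 7 was 0.15, the mean -0.35 and the direction of the camera test down (adjusted p = 0.109, or 0.0289 without KO replicate 1). Within pairs 1 to 3 the medians were 0.17, -0.10 and 0.11. Myeloid markers had a median of 0.32 over 16 genes, 0 of them with a fitted value below 0, and medians of 0.22, 0.54 and -0.07 within pairs 1 to 3. Examples were Vcam1 at 0.39 ± 0.48 and Csf1r at 0.34 ± 0.45. Camera called the list higher with the replicate block (adjusted p = 0.000261 against 0.123 without it; adjusted p = 0.795 with the block and an estimated correlation) and without control replicate 2 (5.45e-05), KO replicate 1 (0.0136), KO replicate 3 (0.000728) or both libraries numbered 2 (0.032). With the block Cd68, Cd14, Adgre1 and Vcam1 were called higher, of which DESeq2 with the block called Adgre1 and Vcam1. Plasma cell (median -0.27, 5 of 5 genes with a fitted value below 0; Txndc5 -0.18, Jchain -0.01), erythroid and platelet (0.24; Itga2b 0.23, Hbb-bs 0.36) and stromal and endothelial markers (-0.66; Pecam1 0.04, Col1a1 -0.69) had 0 called members and adjusted p-values of 0.484, 0.233 and 0.184 by camera. The erythroid and platelet list was called higher without control replicate 3 (adjusted p = 0.0495) or KO replicate 2 (0.0112), and the stromal list lower without KO replicate 1 (0.0313). Only 4 of the 15 stromal and endothelial markers were tested, so the median of that list rests on few genes.

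Over the 36 tested lists, camera called 7 lower and 1 higher with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05, and fry called 3 lower and 0 higher. With the block camera called 7 lower and 2 higher. The number of lists called lower was 4 without control replicate 2 or KO replicate 3, 11 without KO replicate 1 and 12 without KO replicate 2; the number called higher was 3 without control replicate 3 and 2 without any 1 of the KO replicates. With both libraries numbered 2 left out, 11 lists were called lower and 1 higher.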

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

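Leaving out both libraries numbered 2, DESeq2 with the replicate block, thinning, the block with a minimum of 2-fold, and the list tests that add the block to an estimated correlation or to fry were chosen only after the result was seen. The 179 called genes kept their direction in every setting in which they were tested. Size factors of DESeq2, upper quartile factors, no filter on low counts, the filter of 1 CPM in 3 libraries and thinning left the numbers of higher and lower genes within 1.5 times, and 171, 159, 176, 168 and 158 of the 179 were called again. DESeq2 called 72 higher and 261 lower, and 3157 of its 16260 adjusted p-values were NA. limma-voom called 3 higher and 136 lower. Without both libraries numbered 2 the counts were 0 and 54, with a minimum of 2-fold 1 and 104, and at an adjusted p under 0.01 0 and 56. With 1 library left out, in fits that did not include the replicate block, the number of higher genes ranged from 0 to 10 and of lower genes from 26 to 166. Fewer samples are part of that drop. As an example, over these fits the log2 fold change of Tfam lay between -1.22 and -0.87 (-1.09 with all libraries). It lay between -1.08 and -0.76 for Icos (-0.97) and between -0.65 and -0.48 for Nrp1 (-0.59). Each of these genes lost its call with any 1 KO replicate left out. A lost call is therefore not by itself a lost effect, and the cause was not tested further. For the other results that did not hold, the cause was not tested.

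With the replicate block, which follows the pairing of same-numbered libraries, 236 genes were called higher and 526 lower, with the block and a minimum of 2-fold 5 and 181, and with DESeq2 and the block 137 and 294. Among the 150 named genes tested, some of them named because the block called them, the block ended 0 calls and added 36, of which DESeq2 with the block called 16, and it changed no other call than those given with the results. Of the 36 lists, camera called 2 higher and 7 lower with the block, 0 and 0 with an estimated correlation, with or without the block, and 2 and 9 with no filter on low counts. The test fry called 0 higher and 3 lower without the block and 0 and 0 with it. Without both libraries numbered 2 camera called 1 higher and 11 lower, and with 1 library left out 1 to 3 higher and 4 to 12 lower. TMM without mtDNA-encoded genes and the alternatives for the mtDNA share were not run, since all mtDNA-encoded protein genes were at 0. Depth limits what can be seen in genes near 0.157 CPM, the level of 3 counts in the shallowest library.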

Other observations

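The families below, the comparison by replicate number, and all tests in this part except the splits for the number of called lists were chosen only after the result was seen. Beyond the fixed lists, the lower genes included several members of 6 families. These families were picked because members had been called lower, so their counts are a description and no test of enrichment. Of 15 tested chemokine receptors 9 fell, among them Ccr10, Cxcr6 and Ccrl2, and of 6 S100 genes 4, with S100a11 lower by a log2 fold change of -1.36 ± 0.17 and S100a10 of -0.62 ± 0.11. Of 26 interleukin receptor chains 5 fell, of 23 TNF ligands and receptors 4, of 8 matrix metalloproteinases 3, which were Mmp9, Mmp14 and Mmp25, and of 22 integrin chains 3. No member was called higher with TMM, DESeq2 or upper quartile factors, and upper quartile factors gave 8 chemokine receptors and 2 integrin chains. With the replicate block 3 integrin chains were called higher and 5 lower, 9 interleukin receptor chains were called lower, and in the families other than integrins 0 were called higher. Several members also belong to the fixed lists, and S100a11 was not called without KO replicate 1 (adjusted p = 0.0621). S100a10 was not called without KO replicate 1 (0.175), KO replicate 2 (0.0744), KO replicate 3 (0.124), control replicate 2 (0.0643) or control replicate 3 (0.0551).

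Some genes differed between replicate numbers in both genotypes. Vcam1 and Csf1r, which macrophages express, stood at 206.5 and 189.4 CPM in control replicate 2 and at 283.5 and 260.4 CPM in KO replicate 2, against 70.51 to 105.2 and 82.96 to 103.5 CPM in the other libraries. Both were also higher in KO than in control within each of the 3 pairs, and Vcam1 was called higher with the replicate block (adjusted p = 0.0233). The platelet chemokine gene Ppbp was at 0 in both replicates 2 and between 2.536 and 5.077 CPM elsewhere. The heat shock gene Hspa1b lay at 53.19 and 13.22 CPM in replicates 3 and between 139.3 and 255 CPM in the other 4 libraries.

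Of the 10 splits of the 6 libraries into 3 and 3, 1 gave at least 179 called genes, the real one; the highest of the others gave 0, with 74 to 1105 genes at an unadjusted p under 0.05 against 1514. Among the 4 splits that part all 3 same-numbered pairs, 1 gave at least 762 genes with the block, the real one, and the highest of the others gave 0. For called lists, 7 of the 10 splits gave at least the real 8, and the highest of the others gave 15. Both numbers of splits are too few for a share under 0.05. The other splits also mix control and KO libraries, so the genotype difference adds to the spread within their groups. Their 0 called genes therefore do not show what chance alone gives.

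The effector and tissue Treg genes were lower in KO, with a median log2 fold change of -0.91. After every library was thinned to the smallest total, 24 genes of the list were still called lower, so these calls did not need the unequal depth. The fit already scaled for depth, so this was a weak test. CD8 T cell or NK cell RNA in the control libraries, which the sort on YFP would remove, could also contribute. The 7 tested markers did not fall together: 3 had a fitted value below 0, and the median was 0.1486 (SD 0.7538). Their mean was -0.35, and Ccl5, at 10.83 CPM in control, and Nkg7 fell. Median and mean differ in sign, so these few markers do not decide the question. The marker medians within pairs 1 to 3 were 0.1651, -0.0969 and 0.1102, so their sign did not hold in each pair. Fewer effector cells among the sorted KO cells may account for the pattern, as may lower expression per cell. The central Treg list had a fitted median of 0.0683, and its medians within pairs had an SD of 0.08. A rise of this list, of any size, could come from either explanation. The list therefore cannot tell them apart. The genotype is the biological difference the design names, and how it would act was not tested.

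Ighm was lower in KO by a log2 fold change of -0.47 ± 0.07. B cell RNA in the control libraries might give this, but the other 14 tested B cell markers had a median of 0.1026 (SD 0.4854), above the change of Ighm by more than that SD. The medians of all 15 within pairs 1 to 3 were -0.1021, 0.3355 and -0.2224, so that median did not stay above 0 in each pair. Cd79a averaged 2.506 CPM in control, while Ighm fell by 151.6 CPM. Ighj1, a joining segment of the same chain, also fell (log2 fold change -2.77 ± 0.29), from 2.07 to 0.2987 CPM. Cd22 and Ighd were lower with the block in edgeR but not in DESeq2, so a small B cell share stays open as a part of the difference.

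Nuclear complex I genes had a median log2 fold change of -0.11. A shift shared with cytoplasmic ribosomal protein mRNAs could give this: complex I minus ribosomal proteins was -0.0758 on average over the 3 pairs (SD 0.0598; -0.07, -0.1383 and -0.0192). All 3 differences lay below 0, and their mean lies between 1 and 2 SD from 0. That SD is the spread of single pairs, and a mean of 3 pairs varies less, so this distance decides nothing. With 3 pairs an exact two-sided sign-flip permutation test cannot go below p = 0.25. A shared shift and a change of complex I alone therefore cannot be told apart.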
